A study of Mus musculus with 44 samples.

How the data were processed

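RNA was measured by RNA-seq in 44 samples of microglia, the resident macrophages of the brain, sorted from whole mouse brain as CD11b+CD45lowLin- cells. Per the labels, 36 libraries came from germ-free (GF) mice, raised without microbes, or specific-pathogen-free (SPF) mice, of both sexes, at a young age (6 to 10 weeks) or an old one (96 to 104 weeks). The other 8 libraries came from SPF males aged 10 weeks given N6-carboxymethyllysine (CML), a modified amino acid formed by glycation, or PBS as its control. Each column was matched to a sample by its name. Read like the other columns, the name of 1 aged SPF male column gives replicate number 1. Without its separators the number could also be read otherwise, so that library carries no number here. In all, 0 columns were left unused. The labels describe separate samples and do not say that each came from a separate animal, so p-values measure the spread between these samples. The sequence of library or sequencing days was not given in the sources used here, and a batch that follows the groups could not be separated from them.

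Per the labels' protocols, RNA from the sorted cells was turned into full-length cDNA and amplified by PCR with a low-input kit (SMARTer v4), and libraries were made by tagmentation (Nextera XT). The protocols describe no molecular identifiers, so PCR copies count as reads and read numbers are not numbers of molecules. The kits do not mark strand, so reads of overlapping or antisense genes cannot be told apart, and genes with near-identical copies (histone genes, MHC genes, Gpr137b and its pseudogene) are uncertain. Per the submitters' processing notes, the tools were FastQC 0.67, Trim Galore 0.4.3, STAR 2.5.2, MultiQC 1.5.0, DESeq2 1.32.0 and R 4.1.0, with the mouse genome mm10 (GRCm38); the roles of the tools, the counting step and the gene annotation were not given in the sources used here.

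The authors deposited 2 tables of normalized counts, a signal per gene symbol and library that is never negative: 18543 genes in the 36 GF and SPF libraries and 15305 genes in the 8 CML and PBS libraries, with 15105 genes in both. The 2 tables were normalized separately, so every test stays within a table, and levels from different tables are not on a common scale. In each library the values were whole multiples of the value of 1 read: after division by that step, 100.0% of the values above 0 came within 0.001 of a whole number. The recovered reads came to 16.5 to 39.1 M reads per library (median 23.8 M) in the GF and SPF table, and 22.7 to 31.6 M (median 24.7 M) in the CML table. The steps corresponded to size factors of 0.6742 to 1.626 and of 0.9027 to 1.295. The gene with most reads took 2.33 to 4.08% of a library's total in the first table and 2.88 to 3.8% in the second. Over 118 pairs of replicates, the chi-square of the recovered reads per degree of freedom was 12.5 to 147.9, where sampling noise gives about 1, so no library repeated another of its group; pairs across groups were not compared.

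Genes with a normalized count of at least 10 in at least 3 libraries were tested, 12994 in the GF and SPF table and 11766 in the CML table. Values were analysed as log2(normalized count + 1) with limma-trend (limma 3.58.1, R 4.3.3) and Benjamini-Hochberg adjustment over all tested genes, at 0.05. The 8 GF and SPF groups were fitted jointly over 36 libraries with 1 mean per group, and CML against PBS on its own 8 libraries. Because 1 is added to every value, a log2 fold change understates the change of a gene with low counts. Levels are given as mean ± SD of the normalized counts. The 14 comparisons were age within each microbiota status and sex, GF against SPF within each age and sex, the differences of these effects, female minus male averaged over the 4 combinations of age and microbiota, and CML against PBS. Lists of 20 gene functions and of markers for 10 other cell types were tested with camera at a preset correlation of 0.01 where at least 5 members were tested, with adjustment over the lists of a comparison, and again with the correlation estimated from the data. Counts of members past the threshold are given over all genes and with p-values adjusted over the list alone.

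Genes named in the text followed a rule: the 6 called genes (3 in the comparisons of females, of sexes and of effects) with the largest log2 fold change in each direction, with a mean of at least 50 in the higher group and no overlap between the libraries of the groups (not asked of the differences of effects and of the sexes). To these came the 2 members with the smallest adjusted p from each function list with at least 2 called members, and 9 genes followed in every comparison (P2ry12, Tmem119, Apoe, Clec7a, Cybb, Sod2, Hmox1, Nfe2l2 and Ager). Predicted genes and pseudogenes were passed over. Some genes that the rule names are not reported here. Any other gene named is said to be chosen after its values were seen. The groups, comparisons, tests, lists, naming rule and most of the alternatives were fixed before the data were examined.

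Of 18743 symbols, 18222 were found in GENCODE M21, 470 through RefSeq names, and 51 stayed of unknown kind. Coordinates are 1-based, on mm10, from GENCODE M21.

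The alternatives were a pseudocount of 8, no filter, quantile normalization, library weights, the replicate number as a block, only the groups of a comparison, edgeR's quasi-likelihood test (edgeR 4.0.16) and DESeq2 1.42.0 on the recovered reads, and each library of a group of up to 5 left out in turn. On the recovered reads edgeR called 2294 genes for age in SPF males, 1761 for age in GF males, 2732 for microbiota in aged males and 0 for CML. Chosen after seeing the data were the aged SPF males numbered 5 to 14 alone, the other 3 aged SPF males alone, aged GF males 3 to 5 alone and 1 and 2 alone, and the mean log2 level of the neutrophil markers as a covariate. The procedure was tested on simulated data with 200 changed genes. With 3 against 3 libraries, as for microbiota in young males, it recovered 60 of 100 genes changed 2-fold and 88 of 100 changed 4-fold, with 6 false calls among 12701 genes. With the libraries of age in SPF males it recovered 76 and 98 of 100, with 6 false calls among 12699 genes, and with those of CML against PBS 72 and 99 of 100, with 9 false calls among 11572 genes. DESeq2 made 15, 23 and 28 false calls in these simulations of age in SPF males, microbiota in young males and CML, and edgeR 9, 3 and 11. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.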

Results

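Gene expression was measured in 44 libraries of microglia sorted from whole mouse brain. The design compares young with aged mice, germ-free (GF) with specific-pathogen-free (SPF) mice and males with females. A separate set measures the response of young SPF males to N6-carboxymethyllysine (CML). Among males there were 3 young SPF, 13 aged SPF, 3 young GF and 5 aged GF libraries. Each of the 4 female groups had 3 libraries, and the CML and PBS groups had 4 each. The recovered depth per library was 20.6 to 26.4 M reads in young SPF males, 18.0 to 35.8 M in aged SPF males, 17.9 to 25.2 M in young GF males and 16.5 to 39.1 M in aged GF males. In females it was 19.3 to 23.7 M (young SPF), 17.7 to 21.1 M (aged SPF), 19.6 to 25.4 M (young GF) and 23.1 to 27.6 M (aged GF). The CML and PBS libraries had 22.7 to 24.8 M and 24 to 31.6 M. Levels are normalized counts (mean ± SD), and adjusted p-values are from limma-trend. Transcripts of the sex chromosomes matched the labels of the 36 GF and SPF libraries. Xist, the RNA that coats the inactive X chromosome, was 2355.3 to 6175 in the 12 female libraries and at most 5.9 in the 24 male libraries. Ddx3y, a Y-linked helicase gene, was 814 to 2510.7 in males and at most 54.1 in females.

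**Figure D1:**
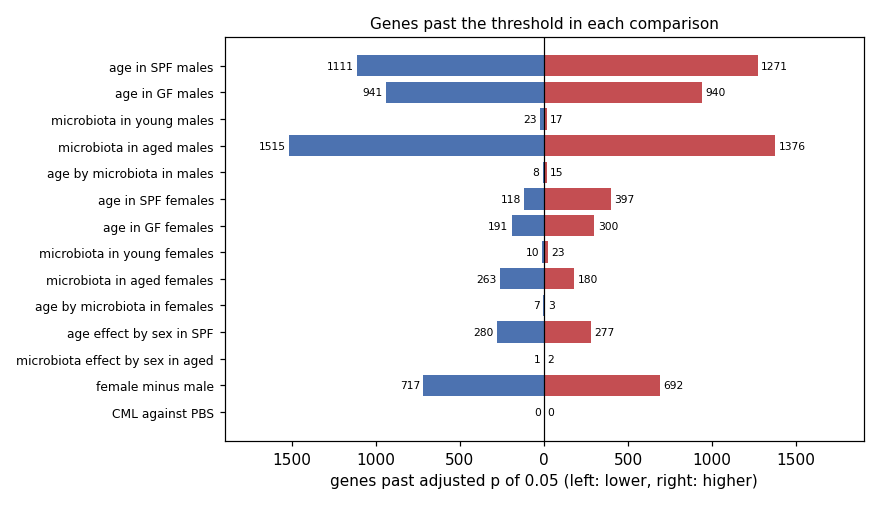
Number of genes past an adjusted p of 0.05 in each comparison (limma-trend), with bars to the right for genes higher in the aged, GF, female or CML group and bars to the left for genes lower there. The bars run from 0 genes for CML against PBS to 1376 higher and 1515 lower for microbiota in aged males.

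In SPF males (13 aged, 3 young), genes of disease-associated microglia (DAM), antigen presentation and antioxidant defence rose with age. Axl, a receptor kinase for the uptake of apoptotic cells, was 3296.6 ± 785 in aged and 306 ± 39 in young males (log2 fold change 3.39, adjusted p = 1.61e-13). Clec7a, a beta-glucan receptor, was 2539 ± 751 against 598 ± 34.6 (2.03, 3.04e-07). H2-Aa, an MHC class II chain, was 1429 ± 736 against 17.3 ± 19.95 (6.86, 6.09e-08). Cybb, the catalytic subunit of the phagocyte NADPH oxidase, was 1014 ± 291 against 47.8 ± 19.5 (4.42, 8.58e-08). Jun, an immediate-early transcription factor, was 2518 ± 944 in aged and 13505 ± 1255 in young males (-2.50, 8.48e-09). Axl lies on chromosome 7 from 25757273 to 25788705 and Clec7a on chromosome 6 from 129461591 to 129472779. H2-Aa lies on chromosome 17 from 34282744 to 34287823 and Cybb on chromosome X from 9435252 to 9487771. In all, 2382 genes differed, 1271 higher and 1111 lower with age.

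The largest increases in aged SPF males were in genes of neutrophil granules. Ngp (chromosome 9, 110419747 to 110423012), a granule protein gene, was 4942.7 ± 5893.7 in aged and 0.865 ± 1.497 in young males. S100a9 was 3064.4 ± 3703.7, Ltf (lactoferrin) 2199.4 ± 2298.5, Chil3 1644.6 ± 1787.0 and Lcn2 991.8 ± 1146.7, and these 4 were listed at 0 in the 3 young libraries. Of 9 tested neutrophil markers, 6 rose (7 adjusted over the list alone, camera adjusted p = 5.08e-08, adjusted p = 0.0515 with an estimated correlation). S100a8, chosen after its values were seen, was above 500 in 12 of the 13 aged SPF male libraries and 0 in aged SPF male 2. Of 11 monocyte markers 3 rose (5 adjusted over the list alone, camera adjusted p = 0.00216, adjusted p = 0.0578 with an estimated correlation). Cxcl13, a B-cell chemokine, was 1789.1 ± 4565.4 against 2.93 in young males, with 16909.5 in aged SPF male 6 and 529.1 ± 470.1 in the other 12 aged libraries. Other cell types were read from their markers in the same way. Higher were 2 of 12 for border-associated macrophages, 3 of 10 for astrocytes, 2 of 9 for the oligodendrocyte lineage, 1 of 8 for endothelial and mural cells and 1 of 2 for B cells. No marker of neurons (11 tested), T and NK cells (2) or erythroid cells (1) was called by limma over all genes. Their tests did not pass (camera adjusted p = 0.124 to 0.905), and the B-cell, T and NK and erythroid lists were too short for a test.

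**Figure D2:**
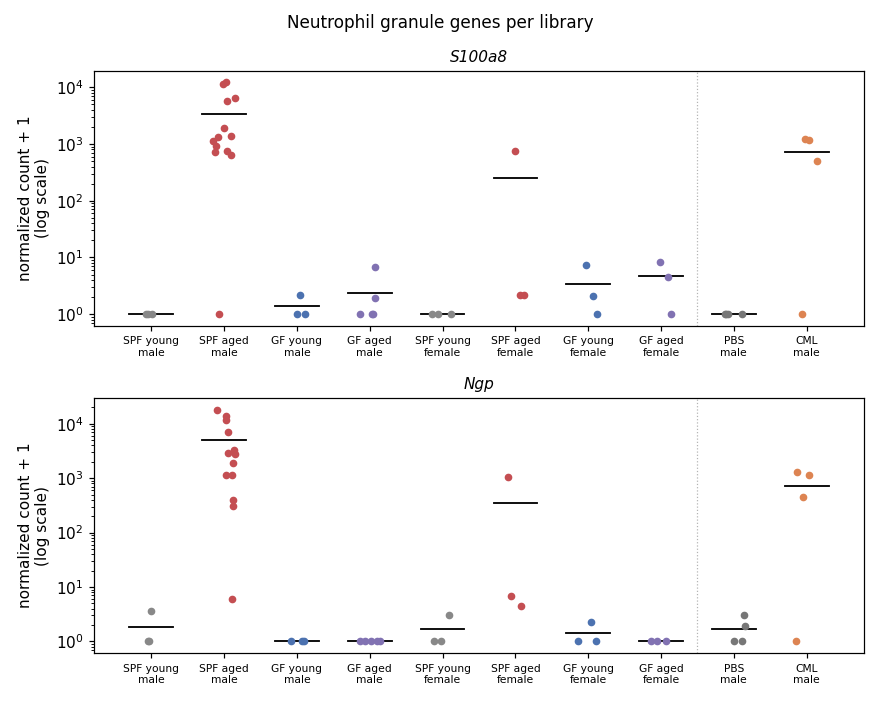
Normalized count + 1 of S100a8 and Ngp in each of the 44 libraries, on a log axis, by group. Each point is a library, the bar is the group mean, and the dotted line parts the tables, which were normalized separately; S100a8 exceeded 500 in 12 of 13 aged SPF males, 1 of 3 aged SPF females and 3 of 4 CML libraries, and was at most 7.3 in every other group.

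Of 27 DAM genes, 16 rose in aged SPF males (21 adjusted over the list alone, camera adjusted p = 4.51e-16), among them Capg at 1708 ± 304 against 575 ± 60.3. MHC and antigen presentation genes rose in 14 of 23 (15 adjusted over the list alone, camera adjusted p = 4.69e-11). Antioxidant genes rose in 11 of 34 (14 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.03e-05), among them the peroxiredoxin Prdx4 at 1886 ± 234 against 950.1 ± 76.9 and the ferritin chain Fth1 at 51281 ± 7528 against 28530.0 ± 3910. These 3 lists also passed with an estimated correlation. Interferon response genes rose in 23 of 37 and fell in 1 (24 higher and 1 lower adjusted over the list alone, camera adjusted p = 3.59e-11, adjusted p = 0.0786 with an estimated correlation). Oasl2 was 832 ± 292 against 110 ± 50.9. Lysosomal genes rose in 17 of 33 (20 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.63e-08, adjusted p = 0.0515 with an estimated correlation). The tetraspanin Cd63 was 6948 ± 607 against 3410.3 ± 247. Complement and Fc receptor genes rose in 7 of 16 (8 adjusted over the list alone, camera adjusted p = 0.000601, adjusted p = 0.0515 with an estimated correlation). C4b was 282 ± 120 against 55.7 ± 23.97. Cytosolic ribosomal protein genes rose in 33 of 69 and fell in 2 (38 higher and 3 lower adjusted over the list alone, camera adjusted p = 7.85e-08, adjusted p = 0.257 with an estimated correlation). Glycolysis genes rose in 11 of 23 (12 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000108, adjusted p = 0.0943 with an estimated correlation). Nuclear oxidative phosphorylation genes rose in 12 of 74 (the same adjusted over the list alone, camera adjusted p = 2.66e-05, adjusted p = 0.425 with an estimated correlation).

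Immediate-early and dissociation stress genes fell in 10 of 24 and rose in 2 (the same adjusted over the list alone, camera adjusted p = 8.01e-06, adjusted p = 0.0629 with an estimated correlation). Fos was 25.3 ± 21.6 in aged and 467 ± 329 in young SPF males. Protein folding genes fell in 6 of 21 and rose in 1 (2 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.0126, adjusted p = 0.181 with an estimated correlation). Hsp90ab1, a cytosolic chaperone, was 12658 ± 2732 against 34578 ± 14999, and Atf4, a stress transcription factor, 1806 ± 390 against 3830.3 ± 195. Inflammatory cytokine and NF-kB target genes rose in 8 of 26 and fell in 3 (10 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.014, adjusted p = 0.167 with an estimated correlation). Tlr2 was 13891 ± 2810 against 5662 ± 734. NADPH oxidase genes rose in 4 of 8 and fell in 2 (the same adjusted over the list alone, camera adjusted p = 0.0165, adjusted p = 0.111 with an estimated correlation). Cell cycle genes rose in 7 of 25 and fell in 1 (8 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000316, adjusted p = 0.0943 with an estimated correlation). The homeostatic microglia, mitochondrial dynamics, sterol and lipid, glycation product receptor and p53 target lists did not pass (adjusted p = 0.0514 to 0.787). The purinergic receptor gene P2ry12 (0.20, adjusted p = 0.267), Tmem119 (0.22, 0.152), the apolipoprotein gene Apoe (-0.05, 0.963), Sod2 (0.26, 0.106), Hmox1 (-0.36, 0.319), Nfe2l2 (0.10, 0.424) and Ager (-1.14, 0.368) did not pass. The count of called genes was 1181 without young SPF male 2, 1326 without young SPF male 3 and 1365 with only the 3 aged SPF males outside numbers 5 to 14, where Tmem119 (0.40, adjusted p = 0.00972) and Apoe (1.497, 0.00288) passed, the latter against -0.51 (0.318) with those numbered 5 to 14 alone. With the neutrophil marker score as a covariate it was 274. Axl, Clec7a, H2-Aa, Cybb, Capg, Oasl2, Cd63, Tlr2 and Jun passed, and C4b, Prdx4, Fth1 and Fos did not. The granule genes lost theirs, but the score itself measures their RNA. The score followed the groups (8.47 ± 2.28 in aged, 1.51 ± 0.111 in young SPF males), and with it standard errors were 1.595 times as large (median over 2365 called genes) and fold changes had a slope of 0.888 across these genes. The log2 fold change went from 2.27 (SE 0.417) to 2.31 (SE 0.673, adjusted p = 0.0617) for C4b and from -4.50 (SE 0.988) to -5.21 (SE 1.585, 0.0776) for Fos. It went from 0.98 (SE 0.134) to 0.69 (SE 0.206, 0.0724) for Prdx4 and from 0.84 (SE 0.13) to 0.61 (SE 0.204, 0.118) for Fth1.

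**Figure D3:**
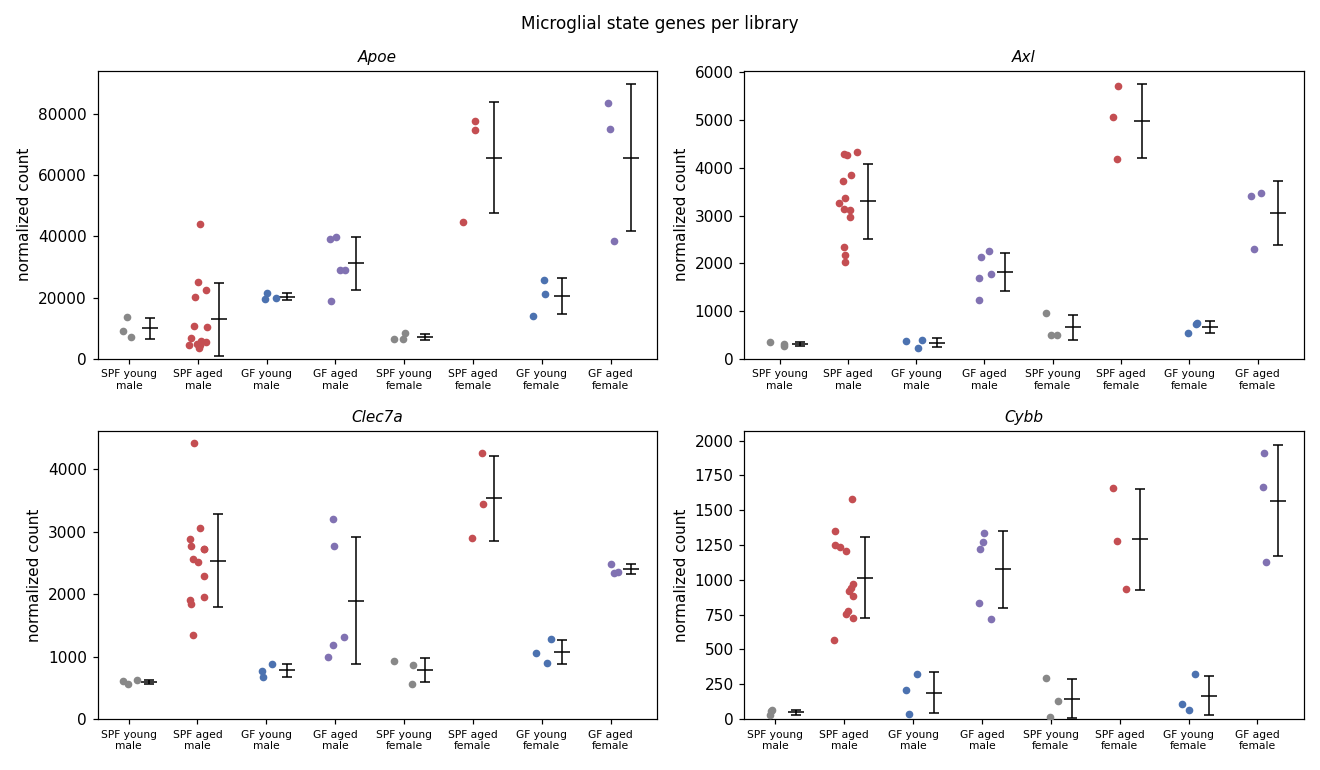
Normalized counts of Apoe, Axl, Clec7a and Cybb in the 36 GF and SPF libraries by group, on linear axes from 0; each point is a library and the bar with caps is the mean ± SD. Axl was 306 ± 39 in young and 3296.6 ± 785 in aged SPF males, and Apoe was 12888 ± 11911 in aged SPF males and 65664.2 ± 18143.2 in aged SPF females.

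In GF males (5 aged, 3 young), 1881 genes differed with age, 940 higher and 941 lower. Axl was 1820 ± 404 in aged and 334 ± 93.4 in young GF males (log2 fold change 2.46, adjusted p = 1.03e-08). Cd74, the invariant chain of MHC class II, was 6260.2 ± 2975 against 793 ± 87.1 (2.83, 1.62e-07), and the complement gene C4b 307 ± 114 against 25.6 ± 9.06 (3.47, 3.95e-06). Cybb was 1076 ± 279 against 189 ± 147 (2.98, 0.000449), and Dlg5, a scaffold protein gene, 194 ± 76.6 against 1.12 ± 1.94 (6.83, 3.57e-09). Lower with age were the histone gene Hist1h2ac (2.77 ± 4.36 against 139 ± 43.2), Fos (68.6 ± 88.9 against 689 ± 582) and Jun (4580 ± 1593 against 13698 ± 1448). None of the 9 neutrophil markers was called by limma (camera adjusted p = 0.986). Aged GF males 1 and 2 stood apart from 3 to 5 in the chi-square of their reads per degree of freedom, which also grows with depth. It was 44.3 between 1 and 2, 19.9 to 34.9 among 3 to 5 and 71.5 to 127.5 across, at depths of 28.7 and 39.1 M reads against 16.5 to 23.1 M. The call of Fos ended with libraries 1 and 2 alone (-2.65, adjusted p = 0.119).

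Lysosomal genes rose in 19 of 33 in aged GF males (23 adjusted over the list alone, camera adjusted p = 2.16e-16). Complement and Fc receptor genes rose in 10 of 16 (12 adjusted over the list alone, camera adjusted p = 1.97e-09), among them C5ar1 at 14707 ± 2710 against 8162 ± 2792. DAM genes rose in 13 of 27 (17 adjusted over the list alone, camera adjusted p = 3.41e-12). MHC genes rose in 14 of 23 (the same adjusted over the list alone, camera adjusted p = 3.41e-12). Antioxidant genes rose in 11 of 34 (15 adjusted over the list alone, camera adjusted p = 1.29e-06). Glycolysis genes rose in 11 of 23 (15 adjusted over the list alone, camera adjusted p = 5.56e-08). NADPH oxidase genes rose in 4 of 8 (6 adjusted over the list alone, camera adjusted p = 5.98e-05). Genes for glycation product receptors and glyoxal detoxification rose in 6 of 19 and fell in 1 (6 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0213). These 8 lists also passed with an estimated correlation. Interferon response genes rose in 8 of 37 (9 adjusted over the list alone, camera adjusted p = 3.74e-06, adjusted p = 0.22 with an estimated correlation). Homeostatic microglia genes rose in 7 of 24 (8 adjusted over the list alone, camera adjusted p = 0.000243, adjusted p = 0.133 with an estimated correlation). Immediate-early genes fell in 7 of 24 and rose in 1 (1 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.00134, adjusted p = 0.181 with an estimated correlation). Protein folding genes rose in 9 of 21 and fell in 1 (11 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.00203, adjusted p = 0.133 with an estimated correlation). Slc2a5, a fructose transporter gene of microglia, was 43073 ± 2317 against 20236 ± 1370 (1.09). Tmem119 was 158917 ± 15857 against 103187 ± 4517 (0.62, adjusted p = 0.000382), and Nfe2l2, a regulator of antioxidant genes, 12226 ± 401 against 8409 ± 724 (0.54, 0.000118). Clec7a was 1893 ± 1015 against 779 ± 107 (1.13, 0.00594, and 0.0547 with only these groups fitted), with 3198 and 2773.7 in aged GF males 1 and 2 and 999.5 to 1308.2 in 3 to 5. With libraries 3 to 5 alone its call ended (0.58, adjusted p = 0.12). P2ry12, Apoe, Sod2, Hmox1 and Ager did not pass (adjusted p = 0.343, 0.545, 0.59, 0.647 and 0.0607). With quantile normalization the homeostatic list lost its call and pointed the other way (adjusted p = 0.191), and Tmem119 (0.17, 0.446) and Nfe2l2 (0.27, 0.0662) lost theirs. The count was 1035 without young GF male 1 and 1169 without young GF male 3.

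Whether age acted differently in GF and SPF males was tested as the difference of the age effects. It passed for 23 genes, 15 higher and 8 lower in GF (17 and 5 with edgeR, 100 and 95 with DESeq2). Hsp90ab1 (chromosome 17, 45567775 to 45573271) was 34578 ± 14999 in young and 12658 ± 2732 in aged SPF males, and 16537 ± 1009 and 17646 ± 3390 in young and aged GF males (difference of log2 fold changes 1.45, adjusted p = 0.0188). The co-chaperone gene Stip1 (1.62, 0.0203) and the HSP70 chaperone gene Hspa8 (1.42, 0.0188) differed the same way. Of 21 protein folding genes 4 passed, all higher (9 adjusted over the list alone, camera adjusted p = 8.65e-10), a list that also passed with an estimated correlation. The granule genes Ngp (-10.11, 0.029) and Camp (-9.84, 0.0351) and the nuclear long noncoding RNA Malat1 (-2.17, 0.0351) differed the other way. Of 9 neutrophil markers 2 were lower (6 adjusted over the list alone, camera adjusted p = 1.32e-09), and this list too passed with an estimated correlation. The count was 1 without young SPF male 2 or 3, 7 without young GF male 1, 10 without 3, 3 without 4, 60 without aged GF male 3, 13 without 4 and 15 without 5. The calls of Stip1, Hsp90ab1 and Hspa8 ended without young SPF male 2 or 3 or young GF male 1 or 4 (0.0552 to 0.114), that of Ngp without any 1 of the 6 young libraries (0.066 to 0.113), and those of Camp and Malat1 without any of these or aged GF male 4 or 5 (0.0541 to 0.113). With only these groups fitted 0 genes passed by limma, against 1702 at an unadjusted p under 0.05 in the joint fit. The count was 723 with the aged SPF males numbered 5 to 14 alone, 8 with the other 3 alone and 14 with quantile normalization. It was 150 with aged GF males 3 to 5 alone and 119 with 1 and 2 alone, where Malat1 did not pass (0.0614).

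In young males (3 GF, 3 SPF), 40 genes differed between GF and SPF, 17 higher and 23 lower in GF (18 and 12 with quantile normalization). Wdfy1, an adaptor of Toll-like receptor signalling (chromosome 1, 79702262 to 79776143), was 2552 ± 305 in GF and 492 ± 27.7 in SPF males (log2 fold change 2.37, adjusted p = 0.000135). Plcd3, a phospholipase C gene (chromosome 11, 103070304 to 103101658), was 94.0 ± 40.7 in GF and listed at 0 in SPF. The protease gene Ctse was 126 ± 88.6 against 2.65 ± 2.40 (4.89, 0.00239). Genes of protein folding were lower in GF, 5 of 21 (13 adjusted over the list alone, camera adjusted p = 1.14e-17), a list that also passed with an estimated correlation. Ero1lb, an oxidase for disulfide formation in the endoplasmic reticulum (chromosome 13, 12565874 to 12611396), was 182 ± 42.3 against 649 ± 150 (-1.83, 0.000135). P4ha1, a prolyl hydroxylase gene (chromosome 10, 59323296 to 59373304), was 7457 ± 110 against 16824 ± 3331 (-1.16, 4.73e-05). The homeostatic microglia list was lower with 1 of 24 called (4 adjusted over the list alone, camera adjusted p = 2.59e-07, adjusted p = 0.102 with an estimated correlation). The cell cycle list was lower with 1 of 25 called (4 adjusted over the list alone, camera adjusted p = 5.06e-05, adjusted p = 0.174 with an estimated correlation). None of the 9 panel genes passed by limma (Apoe 1.08, adjusted p = 0.993, Cybb 1.54, 0.675, P2ry12 -0.32, 0.852), and none of the neutrophil markers was called. With only these groups fitted Apoe passed (0.0345). The count was 14, 20, 19, 25 and 19 without young SPF male 2, young SPF male 3 and young GF male 1, 3 and 4, and 73 without the filter. Mcur1, a mitochondrial calcium uniporter regulator (1556 ± 257 against 2995 ± 320.2, 0.00392), lost its call without young GF male 1 (0.0625). Sdf2l1 (3422 ± 245 against 5445 ± 911, 0.00392) lost it without young SPF male 3 (0.0923), and Pdia6 (12146 ± 373 against 18399.7 ± 1911, 0.00663) without young SPF male 2 or 3 (0.0626 to 0.0929) and with quantile normalization (0.0792).

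In aged males (5 GF, 13 SPF), 2891 genes differed, 1376 higher and 1515 lower in GF. Wdfy1 was 2829 ± 320 in GF and 279 ± 123 in SPF (log2 fold change 3.46, adjusted p = 1.48e-13). Sult1a1, a sulfotransferase gene (chromosome 7, 126672865 to 126676432), was 6657 ± 2262 against 2081 ± 269 (1.63, 7.47e-11). Notch4 was 1108 ± 412 against 261 ± 82.4 (2.05) and the crystallin gene Crybb1 13101 ± 1378 against 6545 ± 1524 (1.03). Fcgr3, an Fc receptor, was 68132 ± 5085 against 41436 ± 4736 (0.72, 3.4e-08), and C5ar1 14707 ± 2710 against 8318 ± 1098 (0.81). Apoe (chromosome 7, 19696109 to 19699188) was 31169 ± 8588 against 12888 ± 11911 (1.70, 0.00201). The granule genes Ngp, Ltf, Lcn2, Cd177 and Hp were listed at 0 in the 5 aged GF males, with Ngp at 4942.7 ± 5893.7 in SPF. Of 9 neutrophil markers 6 were lower in GF (the same adjusted over the list alone, camera adjusted p = 1.52e-06, adjusted p = 0.302 with an estimated correlation). The DAM genes Cd9 (36978 ± 8141 against 55773 ± 6756) and Cst7 (403 ± 290 against 1007 ± 309) were lower in GF. The DAM list as a whole had 5 higher and 5 lower of 27 (5 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.789).

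Ribosomal protein genes were lower in aged GF than aged SPF males in 20 of 69 (24 adjusted over the list alone, camera adjusted p = 2.79e-06, adjusted p = 0.646 with an estimated correlation). Interferon response genes were lower in 8 and higher in 2 of 37 (2 higher and 12 lower adjusted over the list alone, camera adjusted p = 0.02, adjusted p = 0.698 with an estimated correlation). Lysosomal genes were higher in 15 and lower in 3 of 33 (16 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.00468, adjusted p = 0.622 with an estimated correlation). Immediate-early genes were higher in 8 and lower in 2 of 24 (the same adjusted over the list alone, camera adjusted p = 0.0148, adjusted p = 0.622 with an estimated correlation). Cell cycle genes were lower in 4 of 25 (3 adjusted over the list alone, camera adjusted p = 0.0312, adjusted p = 0.622 with an estimated correlation). Nfe2l2 was higher (12226 ± 401 against 9788 ± 1001, adjusted p = 0.000831) and P2ry12 lower (-0.31, 0.0207). Tmem119, Clec7a, Cybb, Sod2, Hmox1 and Ager did not pass (adjusted p = 0.305, 0.0605, 0.896, 0.903, 0.922 and 0.144). P2ry12 lost its call without aged GF male 3, 4 or 5 (0.0527 to 0.107), and Clec7a passed with the aged SPF males numbered 5 to 14 alone (0.0123) and with aged GF males 3 to 5 alone (-1.08, 0.000301). With aged GF males 1 and 2 alone the count was 1566 (579 higher, 987 lower), and P2ry12 (0.691), Cd9 (0.103) and Cst7 (0.419) did not pass. It was 462 with the 3 aged SPF males outside numbers 5 to 14 alone. There Apoe (0.16, adjusted p = 0.814), P2ry12 (0.815), Nfe2l2 (0.0826) and Cd9 (0.108) did not pass, and Wdfy1, Sult1a1, Notch4, Crybb1, Fcgr3, C5ar1 and Cst7 did. It was 1847 with only these groups fitted and 44 with the neutrophil marker score as a covariate, where Wdfy1, Sult1a1, Notch4, Crybb1, Fcgr3 and C5ar1 passed. The score was 2.08 ± 0.16 in aged GF and 8.47 ± 2.28 in aged SPF males and so followed the groups, and with it standard errors were 1.708 times as large (median over 2874 called genes) and fold changes had a slope of 0.806 across these genes. Apoe went from 1.70 (SE 0.391) to 1.28 (SE 0.671, adjusted p = 0.496) and Cst7 from -1.59 (SE 0.291) to -1.81 (SE 0.5004, 0.105).

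**Figure D4:**
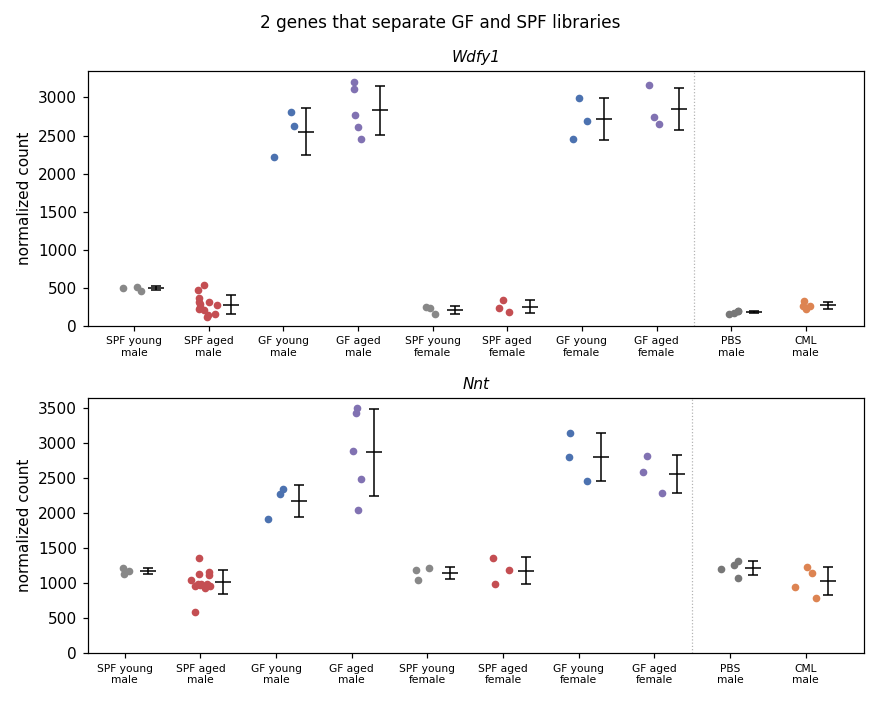
Normalized counts of Wdfy1 and Nnt (the latter chosen after its values were seen) in all 44 libraries by group, on linear axes from 0; each point is a library, the bar with caps is the mean ± SD, and the dotted line parts the tables, which were normalized separately. Wdfy1 was 2218 to 3197 in the 14 GF libraries and 121.9 to 536.5 in the 22 SPF libraries of the first table.

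In SPF females (3 aged, 3 young), 515 genes differed with age, 397 higher and 118 lower. Apoe was 65664.2 ± 18143.2 in aged and 7146.8 ± 1063.6 in young females (log2 fold change 3.17, adjusted p = 0.000871), Clec7a 3534.6 ± 680.4 against 785.6 ± 192.1 (2.18, 1.75e-05) and Cybb 1291.4 ± 363.7 against 147.3 ± 141.8 (3.84, 0.000163). Rab7b, a late endosomal GTPase gene, was 259 ± 123 against 0.345 ± 0.597 (7.58, 1.06e-07) and Gpnmb, a lysosomal glycoprotein gene, 147 ± 29.3 against 0.345 ± 0.597 (6.84, 0.00808). The prostaglandin receptor gene Ptger4 was 156 ± 64.3 in aged females and listed at 0 in young ones. Gnat1, rod transducin, was 151 ± 32.8 in young females and listed at 0 in aged ones. P2ry12 was lower (195329.8 ± 11935.0 against 282295.0 ± 2496.1, 0.0379), a call lost without any 1 of the 6 libraries (0.059 to 0.151) and without the filter (0.0746). Tmem119, Sod2, Hmox1, Nfe2l2 and Ager did not pass (adjusted p = 0.948, 0.913, 0.263, 0.838 and 0.464).

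DAM genes rose in 18 of 27 in aged SPF females (22 adjusted over the list alone, camera adjusted p = 1.98e-28). Interferon response genes rose in 24 of 37 (28 adjusted over the list alone, camera adjusted p = 1.78e-26), MHC genes in 8 of 23 (13 adjusted over the list alone, camera adjusted p = 7.06e-13) and inflammatory genes in 5 of 26 (12 higher and 1 lower adjusted over the list alone, camera adjusted p = 4.5e-07). Complement and Fc receptor genes rose in 4 of 16 (the same adjusted over the list alone, camera adjusted p = 0.00017). These 5 lists also passed with an estimated correlation. Lysosomal genes rose in 5 of 33 (13 adjusted over the list alone, camera adjusted p = 5.27e-08, adjusted p = 0.0549 with an estimated correlation). Of 9 neutrophil markers 1 was called (the same adjusted over the list alone, camera adjusted p = 0.00434, adjusted p = 0.268 with an estimated correlation), with S100a8 at 742.2 in aged SPF female 1 and 1.2 in the other libraries of its group. The count of called genes was 242 without aged SPF female 1, 338 without young SPF female 3 and 274 without young SPF female 4. With only these groups fitted it was 1214 (751 higher, 463 lower).

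In GF females (3 aged, 3 young), 491 genes differed with age, 300 higher and 191 lower. Xdh, a xanthine oxidoreductase gene, was 616 ± 191 against 2.03 ± 2.65 (log2 fold change 8.01, adjusted p = 1.86e-05). Ch25h, which makes 25-hydroxycholesterol, was 334 ± 131 against 3.19 ± 5.53 (7.18, 3.3e-05), and the adhesion molecule gene Alcam 115 ± 1.11 against 0. Cybb was 1570.1 ± 401.1 against 168.7 ± 139 (3.49, 0.000629). Gnat1 was 133 ± 40.5 in young GF females and listed at 0 in aged ones, and the transcription factor gene Tfec was 54.6 ± 9.85 and 0. DAM genes rose in 9 of 27 (13 adjusted over the list alone, camera adjusted p = 4.96e-11). Complement and Fc receptor genes rose in 5 of 16 (7 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000313) and glycation product receptor genes in 2 of 19 (4 adjusted over the list alone, camera adjusted p = 0.0178). Protein folding genes fell in 8 of 21 (the same adjusted over the list alone, camera adjusted p = 1.61e-07). These 4 lists also passed with an estimated correlation. Interferon response genes rose in 4 of 37 (7 adjusted over the list alone, camera adjusted p = 7.84e-09, adjusted p = 0.132 with an estimated correlation). Clec7a (1.17, 0.0302) and P2ry12 (-0.58, 0.0199) were called. Clec7a lost its call without any library but young GF female 2 (0.0683 to 0.132), and P2ry12 without aged GF female 1 or young GF female 2 or 3 (0.0725 to 0.157) and with quantile normalization (0.104). Tmem119, Apoe, Sod2, Hmox1, Nfe2l2 and Ager did not pass (adjusted p = 0.947, 0.14, 0.738, 0.758, 0.175 and 0.933), and with only these groups fitted Apoe did (0.00461). The count was 271 without aged GF female 1, 325 without aged GF female 3, 267 without young GF female 3 and 783 with only these groups fitted.

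In young females (3 GF, 3 SPF), 33 genes differed between GF and SPF, 23 higher and 10 lower in GF. Ddit4, a stress-induced inhibitor of mTOR signalling (chromosome 10, 59949669 to 59951834), was 1302 ± 218 in GF and 69.3 ± 17.3 in SPF (log2 fold change 4.23, adjusted p = 0.000651), and Wscd1 was 119 ± 16.4 against 373 ± 75.4 (-1.64, 0.000469). Camk2b, a calmodulin-dependent kinase gene, was 296 ± 95.3 against 25.2 ± 26.0, Ctse 57.6 ± 18.2 against 3.39 ± 5.00 and Ero1lb 364 ± 42.3 against 845 ± 196. Camk2b lost its call without young SPF female 1 or young GF female 2 or 3 (0.059 to 0.309) and Ctse without young SPF female 3 or 4 or young GF female 3 (0.063 to 0.164), and both with edgeR (0.0787 and 0.0861). Ero1lb lost its call without any library but young SPF female 4 (0.083 to 0.32). None of the 9 panel genes passed by limma (adjusted p of 0.641 for Apoe and higher for the others), and with only these groups fitted Apoe did (0.00174). The ribosomal protein list alone passed, lower in GF with 0 of 69 called (the same adjusted over the list alone, camera adjusted p = 0.029, adjusted p = 0.955 with an estimated correlation). The count was 21 without young SPF female 3, 19 without young GF female 5, 21 with edgeR and 68 with only these groups fitted.

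In aged females (3 GF, 3 SPF), 443 genes differed, 180 higher and 263 lower in GF. Zbtb16, a glucocorticoid-induced transcription factor gene, was 346 ± 205 in GF and listed at 0 in SPF (adjusted p = 0.000313). Hif3a was 285 ± 175 against 2.70 ± 4.67 (6.93, 0.00533, with 0.0955 by edgeR and 0.0514 by DESeq2). Pcdhgb1, a protocadherin gene, was 2.07 ± 3.59 in GF and 65.3 ± 41.2 in SPF (-4.84, 0.0091), and lost its call without aged SPF female 1 or aged GF female 2 or 3 (0.0574 to 0.0657). Interferon response genes were lower in GF in 5 of 37 (11 adjusted over the list alone, camera adjusted p = 1.14e-08, adjusted p = 0.397 with an estimated correlation). Inflammatory genes were lower in 8 and higher in 1 of 26 (2 higher and 12 lower adjusted over the list alone, camera adjusted p = 0.00161, adjusted p = 0.397 with an estimated correlation). DAM genes were lower in 3 of 27 (8 adjusted over the list alone, camera adjusted p = 0.00161, adjusted p = 0.408 with an estimated correlation). No neutrophil marker was called by limma over all genes (2 adjusted over the list alone, camera adjusted p = 0.0149, adjusted p = 0.408 with an estimated correlation). None of the 9 panel genes passed (adjusted p of 0.339 for Hmox1 and higher for the others), with Apoe at 65664.0 ± 23920.3 in GF and 65664.2 ± 18143.2 in SPF; with only these groups fitted Clec7a did (-0.54, 0.0289). The count was 235 to 289 when any 1 of the 6 libraries was left out, 681 with DESeq2 and 1014 with only these groups fitted.

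The difference of the age effects between GF and SPF females passed for 10 genes, 3 higher and 7 lower (3 and 3 with quantile normalization, 1 and 4 with edgeR). Sult1a1 was 3669 and 10409.9 in young and aged GF females and 1685 and 1678 in SPF (difference of log2 fold changes 1.53, adjusted p = 0.0299). Relb, an NF-kB subunit gene (chromosome 7, 19606217 to 19629438), was 486 and 191 in young and aged GF and 580.3 and 876 in SPF females (-2.02, 0.0265). The tropomodulin gene Tmod1 (3.46, 0.0465), Ttyh2 (-2.35, 0.0465) and the chloride cotransporter gene Slc12a2 (-1.46, 0.0395) passed too. Leaving out any 1 of the 12 libraries ended the call of Ttyh2 unless it was aged GF female 2, that of Tmod1 unless it was aged or young SPF female 1, and that of Sult1a1 unless it was young SPF female 4, aged GF female 2 or young GF female 5 (adjusted p up to 0.166). Slc12a2 kept its call without aged SPF female 2, young SPF female 1, aged GF female 2 or young GF female 5, and Relb lost it without aged SPF female 1 or 3, young SPF female 3, aged GF female 1 or young GF female 2 or 3 (up to 0.156). The count was 0 to 9 when any 1 library was left out, and 985 genes had an unadjusted p under 0.05. No member of any list was called by limma over all genes, and no list test that passed did so with an estimated correlation. The DAM (camera adjusted p = 1.39e-06, adjusted p = 0.324 with an estimated correlation) and interferon response lists (adjusted p = 1.39e-06, adjusted p = 0.393 with an estimated correlation) had the smallest values.

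The age effect in SPF mice differed between females and males for 557 genes, 277 higher and 280 lower in females. Hist1h2ac (6.21, adjusted p = 0.00291), the kinesin gene Kif23 (6.91, 0.0238) and Fos (5.75, 0.034) were higher. Gnat1 (-7.30, 1.74e-07) and Chil3 (-8.04, 0.0497) were lower. Immediate-early genes were higher in 7 of 24 (12 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.77e-06, adjusted p = 0.262 with an estimated correlation). No neutrophil marker was called by limma over all genes (1 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.0132, adjusted p = 0.605 with an estimated correlation). The count was 189 to 403 when any 1 of the 3 young male and 6 female libraries was left out. It was 118 with the 3 aged SPF males outside numbers 5 to 14 alone and 1691 with those numbered 5 to 14 alone. Kif23 lost its call without young SPF male 2, aged SPF female 2 or 3 or young SPF female 4 (0.0555 to 0.089). Fos kept its call only without young SPF male 4 or aged SPF female 2, and Chil3 only without aged or young SPF female 1 (otherwise up to 0.095 and 0.202).

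The microbiota effect in aged mice differed between the sexes for 3 genes. Relb was 191 in GF and 876 in SPF females and 449.5 and 656 in males (-1.74, adjusted p = 0.0178). The cytokine receptor gene Lifr was 6078 and 2925 in females and 3122 and 3708 in males (1.28, 0.0346), and Tcf7l2 2187 and 1101 in females and 1518 and 1405 in males (0.88, 0.048). All 3 lost their call without aged GF male 4 or 5, aged SPF female 1 or aged GF female 1 (0.0522 to 0.14). Relb also lost it without aged GF female 2, Lifr without aged SPF female 2 or aged GF female 3, and Tcf7l2 without any of these. The count was 0 to 76 when any 1 of 11 libraries was left out, 0 by limma with the 3 other aged SPF males alone and 664 with those numbered 5 to 14 alone. It was 627 with aged GF males 3 to 5 alone, and with 1 and 2 alone Relb, Lifr and Tcf7l2 did not pass (0.0735 to 0.0815). No list had a member called by limma over all genes, and no list test that passed did so with an estimated correlation. The lysosomal list was among those with the smallest value (camera adjusted p = 6.8e-07, adjusted p = 0.233 with an estimated correlation).

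Averaged over age and microbiota, 1409 genes differed between the sexes, 692 higher and 717 lower in females. Another split of the same libraries called 1596, so a count of this size need not come from sex. Xist (10.95) was higher and the Y-linked genes Ddx3y (-9.96), Eif2s3y (-9.37) and Uty (-8.99) lower in females. Lysosomal genes were higher in females in 24 of 33 (28 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.47e-20). DAM genes were higher in 20 of 27 (24 adjusted over the list alone, camera adjusted p = 1.38e-18). Complement and Fc receptor genes were higher in 9 of 16 (12 adjusted over the list alone, camera adjusted p = 2.07e-07), antioxidant genes in 7 of 34 (9 adjusted over the list alone, camera adjusted p = 2.05e-05) and genes of mitochondrial dynamics and quality control in 3 of 24 (the same adjusted over the list alone, camera adjusted p = 0.0115). These 5 lists also passed with an estimated correlation. Nuclear oxidative phosphorylation genes were higher in 16 of 74 (29 adjusted over the list alone, camera adjusted p = 6.41e-14, adjusted p = 0.181 with an estimated correlation). Homeostatic microglia genes were higher in 8 and lower in 1 of 24 (11 higher and 1 lower adjusted over the list alone, camera adjusted p = 6.99e-06, adjusted p = 0.0781 with an estimated correlation), a list that turned the other way with quantile normalization (adjusted p = 0.295).

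CML was compared with PBS in young SPF males (4 against 4). Limma called 0 of 11766 genes (953 at an unadjusted p under 0.05), edgeR 0 and DESeq2 50 (23 higher, 27 lower). In simulation with 200 changed genes DESeq2 made 28 false calls, which cannot rate the 50 here. The complement gene C4b (chromosome 17, 34728380 to 34743882) was 106 ± 39.1 with CML and 458 ± 191 with PBS (log2 fold change -2.10, adjusted p = 0.124, and 5.04e-07 with DESeq2). Vat1l was 0.791 against 38.2 ± 21.6 (-4.36, 0.383, and 0.00119 with DESeq2), and the noncoding gene Snhg17 71.0 ± 12.5 against 17.6 ± 2.70 (1.95, 0.383, and 0.00285 with DESeq2). Cybb was 219.8 ± 106 against 363 ± 25.1 (-0.88, 0.54) and Hmox1, heme oxygenase 1, 599 ± 165 against 879 ± 193 (-0.57, 0.54). Ager, the receptor for glycation products, was 14.1 ± 6.83 against 4.56 ± 5.93 (2.04, 0.617). P2ry12, Tmem119, Apoe, Clec7a, Sod2 and Nfe2l2 had adjusted p of 0.753 to 0.987.

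No list member passed by limma over all genes with CML. Of 7 neutrophil markers, 6 passed adjusted over the list alone, all higher with CML (camera adjusted p = 1.4e-08, adjusted p = 0.351 with an estimated correlation). S100a8 and Ngp, chosen after their values were seen, were 721 ± 579 and 728 ± 616 with CML (adjusted p = 0.385 for both). S100a8 was listed at 0 in the 4 PBS libraries and in CML library 4, and Ngp was 0.735 with PBS. The protein folding list was lower (1 adjusted over the list alone, camera adjusted p = 1.35e-05, adjusted p = 0.351 with an estimated correlation). The border-associated macrophage list was higher (adjusted p = 0.000316, adjusted p = 0.375 with an estimated correlation), as was the nuclear oxidative phosphorylation list (adjusted p = 0.000505, adjusted p = 0.849 with an estimated correlation). The interferon response list was lower (adjusted p = 0.00376, adjusted p = 0.43 with an estimated correlation). The antioxidant (adjusted p = 0.823), NADPH oxidase (0.991), mitochondrial dynamics (0.291), glycation product receptor (0.736) and DAM (0.548) lists did not pass. The count was 8 without CML library 4, 206 with library weights (81 higher, 125 lower) and 3 without the filter. It was 43 with the neutrophil marker score as a covariate, where C4b (-2.88, adjusted p = 0.0107) and Cybb (-2.00, 0.012) passed.

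**Figure D5:**
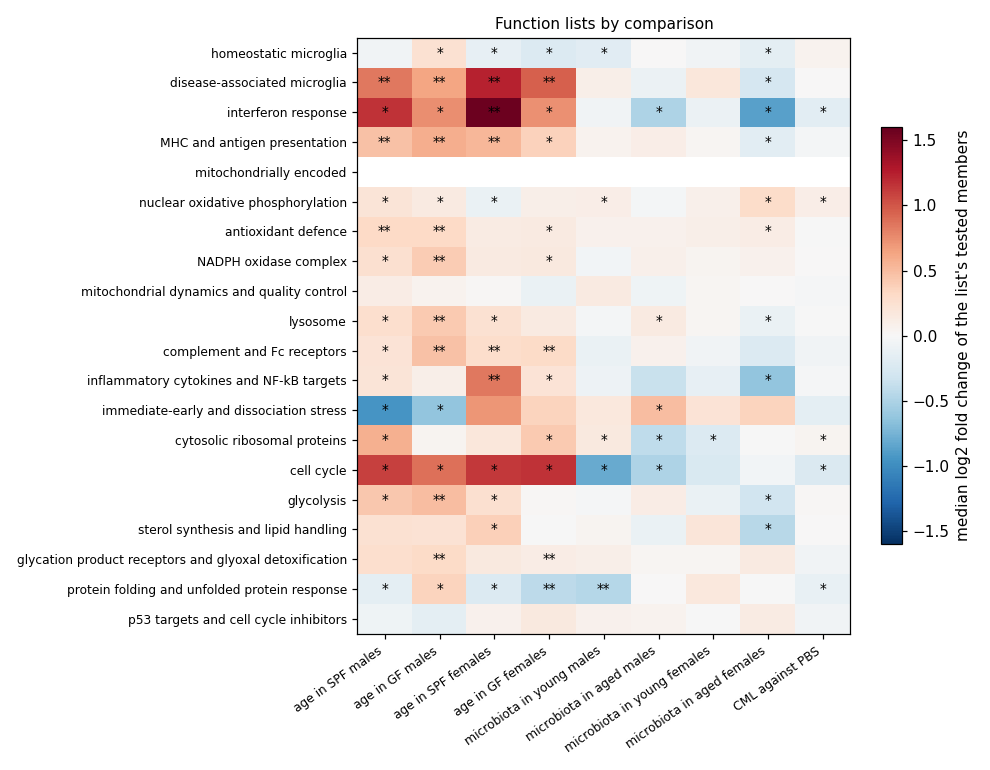
Median log2 fold change of the tested members of the 20 function lists (vertical axis) in 9 comparisons (horizontal axis), from blue (lower) to red (higher in aged, GF or CML); one asterisk marks a camera adjusted p under 0.05, a pair of asterisks a list that also passed with an estimated correlation, and the white row was not tested. The DAM list carries a pair of asterisks in each of the 4 age comparisons and no asterisk for CML against PBS.

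Age effects were set beside each other across comparisons that share no library, with genes not taken as independent replicates. Between SPF and GF males, 485 genes rose in both (91.95 for independent lists), 383 fell in both (80.46) and 4 moved in opposite directions (172.4). Their log2 fold changes correlated across genes (Pearson 0.535, Spearman 0.486). Between SPF males and SPF females 223 rose in both (38.83), 20 fell in both (10.09) and 15 went opposite ways (45.49). The 1271 genes that rose in SPF males were higher in aged SPF females as a set (65.5% positive, camera adjusted p = 6.32e-11, and 0.0249 with an estimated correlation). The 1111 genes that fell did not pass as a set there (adjusted p = 0.0565). The 397 genes that rose in SPF females were higher in aged GF males (332 positive, adjusted p = 1.73e-28, and 7.45e-05 with an estimated correlation). They did not pass as a set between aged GF and SPF males (200 positive, adjusted p = 0.894). With CML, 48.7% of the genes that rose with age in SPF males were positive (adjusted p = 0.92), and the fold changes of age and of CML had a Pearson correlation of 0.0746 and a Spearman correlation of -0.00454 across genes (0.258 and 0.0174 over the 9155 genes with a mean of at least 100 in both tables, which were normalized separately). Between aged males and aged females, 106 genes were higher in GF in both (19.06), 144 lower in both (30.66) and 2 opposite (48.84).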

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

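The tests of mature neutrophil and immature granulocyte RNA and of a strain or colony variant, the slope with the neutrophil marker score, all counts of other splits, and the fits with a part of the aged SPF or aged GF males or with the neutrophil marker score were chosen after the results were seen.

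Transcripts of neutrophil granules were present in most aged SPF males. S100a8 exceeded 500 in 12 of 13 aged SPF males (highest 12164.7, and 0 in aged SPF male 2), 1 of 3 aged SPF females (742.2) and 3 of 4 CML libraries (highest 1207.8), and was at most 7.3 in every other group. Genes of mature neutrophils had a mean level of 9.14 over 8 genes in aged SPF males, 0.339% of the mean of 2700.9 for the granule genes, among them S100a8 and S100a9. No neutrophil libraries were at hand to give the ratio that mature neutrophils would show. This value therefore decides nothing about RNA of mature neutrophils. The mean levels of 17 immature granulocyte genes in aged SPF males and in CML libraries had a Spearman correlation of 0.98 across genes, but random sets of as many tested genes had a median of 0.971 and a share of 0.348 of them were as high, so this decides nothing about RNA of immature granulocytes, and Mpo, Elane, Prtn3 and Ctsg (means of 14.5, 37.8, 5.17 and 1.74, chosen after their values were seen) were not among the 17. A source at either stage stays open. Whether the RNA came from cells inside the gate of CD45-low, lineage-negative cells, which would remove granulocytes, or from free RNA, was not tested. Whether age or an unrecorded batch brought it was not tested either.

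Differences between GF and SPF mice that both ages and sexes shared are a second pattern, with 24 genes called in at least 3 of the 4 comparisons, 11 of them in all 4 and 23 with the same sign in all 4. Several did not overlap between the 14 GF and 22 SPF libraries: Wdfy1 (2218 to 3197 in GF, 121.9 to 536.5 in SPF), Nnt (1919 to 3499, 585 to 1364), Gpr137b-ps (102 to 154, 976 to 1474) and Ero1lb (136 to 406, 477 to 1055), of which Nnt and Gpr137b-ps, with Gpr137b below, were chosen after their values were seen. The 22 genes with a position held 4 pairs within 5 Mb, against a median of 1 in 10000 random sets of that size and a share of 0.0576 of sets with as many. On chromosome 13, Ero1lb (12565874 to 12611396) and Gpr137b-ps (from 12615057) lie close together. Both were lower in GF in all 4 comparisons, and Gpr137b near them was higher in all 4. A strain or colony variant may contribute but cannot be told apart from an effect of microbiota with this number of genes. Gpr137b (chromosome 13, 13357620 to 13394014) rose where its pseudogene Gpr137b-ps (13, 12615057 to 12650388) fell, and the sum of both separated GF from SPF libraries in 0 of 4 comparisons but differed by more than the SD of either group in aged females (1667 ± 298 in GF, 2165 ± 450.1 in SPF), unlike in the other 3, so reads shared between the near-identical copies cannot be told apart from a change of either gene. An effect of microbiota, which the design names, stays open and untested.

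The aged SPF males numbered 5 to 14 gave more calls against aged GF males (4161 genes) than the 3 others (462), and 2433 genes differed between the 10 and the 3 libraries, where 98 other splits of the same sizes had a median of 1 and a highest value of 914. Apoe was 8112 ± 6403 in the 10 and 28808 ± 13132 in the 3 libraries, and Malat1 96078 and 44154. Draws of 3 libraries from the 10 gave a median of 2745 calls over 39 draws (1671 to 3226), which argues against the number of libraries as the reason, and with the neutrophil marker score in the fit of the 10 against aged GF males, the fold changes of 3859 genes called only with the 10 had a slope of 0.898 on those without it (0.876 to 0.959 without any 1 of the 10), which argues against neutrophil RNA as the whole reason, although 338 genes passed there, with standard errors 2.37 times as large. Of the 3869 genes called only with those numbered 5 to 14, 69.3% pointed the same way in aged females, which argues against a batch as the whole reason, while the genes called with both parts reached 91.1% of 292 and those called only with the 3 others 87.7% of 170. The lower share leaves open that a batch may account for part of the calls, and a difference between animals stays open, since the labels give neither a date nor a batch.

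Differences of the effects of age or of microbiota were called, but the counts moved without 1 library (ranges in brackets). Between GF and SPF males the difference of age effects passed for 23 genes (1 to 60). Log2 values were Stip1 1.62, Hsp90ab1 1.45, Hspa8 1.42, Ngp -10.11, Camp -9.84 and Malat1 -2.17. Between GF and SPF females it passed for 10 (0 to 9), with Tmod1 3.46, Sult1a1 1.53, Ttyh2 -2.35, Relb -2.02 and Slc12a2 -1.46. Between the sexes in SPF mice it passed for 557 (189 to 403), with Kif23 6.91, Hist1h2ac 6.21, Fos 5.75, Chil3 -8.04 and Gnat1 -7.30. Between the sexes in aged mice the difference of microbiota effects passed for 3 (0 to 76), with Lifr 1.28, Tcf7l2 0.88 and Relb -1.74.

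Single libraries lay far from the others of their group by Dixon's ratio, the gap to the nearest library over the range of the group, in 9 of 51 checks, where chance gives about 2.55. Of the 5 aged GF males, library 5 was apart for Hist1h2ac (ratio 0.711, 10.3 against at most 2.97) and Ager (0.734, 9.23 against at most 2.46), and library 1 for Hist2h2bb (ratio 1, 8.63 against 0). Library 3 was apart for Hist1h1d (0.833, 3.69 against at most 0.615), library 4 for Chil1 (0.711, 20.8 against at most 9.5), and library 2 for Fndc7 (0.882, 10.5 against at most 1.23) and Sult1a1 (0.745, 10575 against at most 6276). CML library 3 was apart for Vat1l (0.925, 0 against at least 1.02) and PBS library 3 for Cybb (0.834, 325.9 against at least 371). Most of these genes were near 0 in that group.

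Other splits of the same libraries into groups of the same sizes were fitted in the same way. The real split of age in SPF males called 2382 genes and the highest other 1216 (1 of 100 splits as large, the real one included). For age in GF males it was 1881 against 1237 (1 of 56) and for microbiota in aged males 2891 against 1764 (1 of 100). Chance is unlikely for these and for age in SPF males. For age by microbiota in males it was 23 against 14 (1 of 100) and for the age effect by sex 557 against 448 (1 of 100). Their other splits exchanged GF and SPF, or the sexes, within each age. They therefore also mixed effects of microbiota or sex that both ages share, and cannot decide whether the age effects differ. Without young SPF male 2 the 23 calls fell to 1. For females against males 1 other split called more, 1596 against 1409 (2 of 100), a share under 0.05. That split gave some libraries the other sex, so a count of this size can also come from a structure of the samples. Chance cannot be excluded for age by microbiota in females (10 against 125, 11 of 100) or the microbiota effect by sex (3 against 1287, 10 of 100). For CML against PBS limma called 0 genes (953 at an unadjusted p under 0.05, 0 calls by edgeR and 50 by DESeq2), so each of the 35 splits is as large by construction (35 of 35, highest other 0) and the count decides nothing. The splits that called 125 and 1287 genes also mixed effects that groups share and decide nothing. The comparisons of 3 against 3 libraries have 10 splits, too few for a share under 0.05: microbiota in young males 40 against 2, age in SPF females 515 against 0, age in GF females 491 against 2, microbiota in young females 33 against 1 and microbiota in aged females 443 against 1, with 1 of 10 as large in each.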

How the results depend on the processing

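The fits with part of the aged SPF or aged GF males and with the neutrophil marker score were chosen after the results were seen; the other alternatives were fixed before the data were examined. The cause of a changed value was not tested unless it is named.

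Values within 1.5 times the reported count are left out here, and each other count is given. Library weights raised the counts to 3990 for age in SPF males, 3014 for age in GF males, 228 for microbiota in young males, 829 for age by microbiota in males, 1238 for age in SPF females, 1076 for age in GF females, 90 for microbiota in young females, 1142 for microbiota in aged females, 87 for age by microbiota in females, 1997 for age by sex, 588 for microbiota by sex, 2576 for females against males and 206 for CML. DESeq2 on the recovered reads called 80 for microbiota in young males, 195 for age by microbiota in males, 64 for microbiota in young females, 681 for microbiota in aged females, 44 for age by microbiota in females, 860 for age by sex, 119 for microbiota by sex and 50 for CML, and edgeR 21 for microbiota in young females, 5 for age by microbiota in females and 5 for microbiota by sex. With only the groups of a comparison fitted, by limma, the counts were 1847 for microbiota in aged males, 0 for age by microbiota in males, 1214 for age in SPF females, 783 for age in GF females, 68 for microbiota in young females, 1014 for microbiota in aged females, 113 for age by microbiota in females, 314 for age by sex and 1 for microbiota by sex. Without the filter they were 73 for microbiota in young males, 1 for age by microbiota in females and 3 for CML, with quantile normalization 14 for age by microbiota in males and 6 for age by microbiota in females and with 8 as the pseudocount 6 for microbiota by sex. With only the aged SPF males numbered 5 to 14 the counts were 723 for age by microbiota in males, 1691 for age by sex and 664 for microbiota by sex. With only the 3 others, by limma, they were 1365 for age in SPF males, 462 for microbiota in aged males, 8 for age by microbiota in males, 118 for age by sex and 0 for microbiota by sex. With only aged GF males 3 to 5 they were 150 for age by microbiota in males and 627 for microbiota by sex, and with only 1 and 2 they were 1566 for microbiota in aged males and 119 for age by microbiota in males. With the neutrophil marker score as a covariate they were 274 for age in SPF males, 44 for microbiota in aged males and 43 for CML, with standard errors 1.598, 1.713 and 1.548 times as large (medians over all genes).

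With 1 library left out, from groups of up to 5 libraries, the counts ran from 1181 to 1673 for age in SPF males, 1035 to 1856 for age in GF males, 14 to 43 and 2029 to 2875 for microbiota in young and aged males, and 1 to 60 for age by microbiota in males. In females they ran from 242 to 366 for age in SPF, 267 to 401 for age in GF, 19 to 30 and 235 to 289 for microbiota in young and aged mice, and 0 to 9 for age by microbiota. They were 189 to 403 for age by sex, 0 to 76 for microbiota by sex, 1082 to 1595 for females against males and 0 to 8 for CML.

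Same-numbered libraries did not deviate together, so the replicate number was not taken to pair them. Their correlations were -0.0101 to 0.0669 in the CML table, -0.0341 to 0.0227 in females and -0.0471 to 0.0966 in males, none over 0.1, and 2 of 4 CML libraries were closest to the PBS library of their own number. With the replicate number as a block, limma called 679 for age in SPF males, 25 for microbiota in young males, 217 for microbiota in aged males, 2 for age by microbiota in males, 304 for age in SPF females, 275 for age in GF females, 9 for microbiota in young females, 0 for age by microbiota in females, 19 for age by sex, 0 for microbiota by sex and 76 for females against males. Numbers 6 to 14 occur only in aged SPF males, so the block takes up these libraries by construction.

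Of 362 list tests, 140 passed at the preset correlation, 28 with an estimated correlation and 130 with quantile normalization. With quantile normalization 21 lists lost their call, 12 gained it and 3 turned: the lysosomal list for microbiota in young males (adjusted p = 0.0142, now called), the homeostatic microglia list for age in GF males (adjusted p = 0.191) and for females against males (adjusted p = 0.295). The 118 genes lower with age in SPF females passed as a set in GF males with quantile normalization (adjusted p = 0.0132, against 0.894). Over the 9155 genes with a mean of at least 100, the correlation of fold changes moved to 0.258 for age in SPF males with CML (Pearson, from 0.0746, with Spearman at 0.0174 from -0.00454), 0.11 for age in SPF males with SPF females (Spearman, from 0.16) and 0.202 for microbiota in young with aged males (Pearson, from 0.142). With the neutrophil score, which measures granule RNA, 4 named genes turned and lost their call: Ltf (-0.40) and Lcn2 (-0.40) for age in SPF males, and Cdc42ep1 (-0.0302) and Cd177 (1.04) for microbiota in aged males. Prkcsh turned for microbiota in aged males with the 3 other aged SPF males alone (-0.26), Apoe for age in SPF males with the same 3 (1.497, now called) and Eif2ak3 for microbiota in aged males with aged GF males 1 and 2 alone (-0.0203). Over the named genes, 209 of the fits with 1 library left out lost a call, 4 gained one and 1606 did neither. Calls were lost for 80 with the replicate block, 62 with the neutrophil score, 43 with the 3 other aged SPF males, 23 with only the groups of a comparison, 22 with aged GF males 1 and 2 alone (9 with 3 to 5 alone), 19 with quantile normalization, 18 with edgeR, 9 without the filter, 6 with a pseudocount of 8 and 3 with DESeq2. The depth of 16.5 to 39.1 M reads per library limits what could be tested, since genes without a normalized count of 10 in at least 3 libraries were left out.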

Other observations

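The test of the clock in young females was chosen after its result was seen, and the genes named were chosen after their values were seen, except Ddit4, Zbtb16 and Gnat1.

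GF females had higher levels of genes that glucocorticoids induce. In aged females Fkbp5, a chaperone of the glucocorticoid receptor, was 13563 ± 3592 in GF and 2329 ± 371 in SPF (adjusted p = 2.66e-05 by limma). Tsc22d3, an induced leucine zipper gene, was 21053 ± 7644 against 2308 ± 325 (adjusted p = 1.65e-06 by limma), and Zbtb16 was 346 ± 205 in GF and listed at 0 in SPF. In aged males Fkbp5 was 4924 ± 2427 against 2228 ± 579 (0.00125) and Tsc22d3 7569.6 ± 2501 against 3381 ± 1492 (0.000617). As a set, 5 of the 13 tested glucocorticoid-induced genes were higher and 3 lower in aged GF males (camera p = 0.0189, 0.142 with an estimated correlation). In young males 0 of 13 were called by limma over all genes (camera p = 0.176, 0.391 with an estimated correlation). Per1, a clock gene that glucocorticoids also induce, was 687 ± 186 against 125 ± 55.8 in aged females and 334 ± 47.9 against 55.9 ± 4.84 in young females.

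A glucocorticoid response may account for Per1 and Ddit4 in GF females. The 13 tested glucocorticoid-induced genes were higher as a set in GF females, by limma and camera, with p = 2.06e-08 in aged mice (0.00118 with an estimated correlation, 5 of 13 called) and p = 0.000324 in young mice (0.0282 with an estimated correlation, 0 of 13 called by limma over all genes). In aged females 10 of the 13 log2 fold changes were positive, the largest for Zbtb16 (8.28) and Hif3a (6.93). Mt2 (-2.39), Mt1 (-0.38) and Cdkn1a (-0.03) pointed the other way. A collection time nearer the peak of the Per phase would raise the Per-phase genes and lower those of the opposite phase. In aged females 4 genes of the opposite phase had a mean log2 fold change of 0.72 (camera p = 0.0248, 0.073 with an estimated correlation). The 10 genes of the Per phase were not higher (mean -0.50, camera p = 0.0896). These values argue against a shift towards that peak as the reason for Per1 there. A shift the other way would move both lists as seen and stays open, but it would lower Per1. In young females the same lists had means of 0.00707 (p = 0.766) and -0.0209 (p = 0.961), which leaves a shift of the clock open at that age. In males the glucocorticoid-induced set did not pass with an estimated correlation at either age. The 10 genes of the Per phase were lower as a set in young GF males (camera p = 0.0122, 0.125 with an estimated correlation). They were also lower in aged GF males, with 5 called lower and 1 higher (camera p = 0.0193, 0.151 with an estimated correlation). The opposite-phase genes did not pass in males (camera p = 0.375 and 0.903). Handling or time of collection was not given in the sources used here.

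Transcripts of rod photoreceptors were present in young females of both kinds. Gnat1, rod transducin, was 86.3 to 161 in the 3 young GF and 121 to 186 in the 3 young SPF female libraries, and at most 1.02 in the other 30 libraries of that table. Prph2, a structural protein of the outer segment, was 20.8 to 45.3 and 28.9 to 38.2. Pdc was 8.92 to 24.5 and 20.4 to 30 and listed at 0 in the others. Sag, the rod arrestin, was 27.8 to 67.1 and 53.7 to 62.5, and was at most 32.4 in the other groups.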
